A study of Crotalus atrox and Pantherophis obsoletus lindheimeri
Masticophis flagellum testaceus and Python regius with 10 samples.

How the data were processed

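RNA was taken from trigeminal and dorsal root ganglia of snakes. Per the labels' protocols, tissue was fixed in paraformaldehyde and extracted with Trizol, and RNA fragments of about 30 bases were tailed with poly(A), reverse transcribed from an anchored oligo(dT) primer and circularized as cDNA. Reads aligned in the files reached position 80 and matched the proteins in forward and reverse orientation in about equal shares (49.5% to 51.4% forward), so strand was not used. The labels name the groups by snake, ganglion and, for rattlesnake and non-pit snakes, the size of the trigeminal ganglion; what large and small stand for is not given in the sources used here. The labels mark the non-pit snakes as such. The rattlesnake is a pit viper, and python and boa were taken as pit-bearing from the design text and from textbook knowledge.

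The deposited files hold, for each library, a table of counts per protein entry and the alignments behind it. The aligner, its version and the source of the protein entries are not given in the sources used here. The deposited alignments are in a tabular form of 12 columns, as BLAST writes it, with translated reads against protein entries and a largest E-value of 8e-06. Their columns give the percent identity as the authors deposited it, the deposited alignment lengths and positions, and a deposited bit score per alignment. The deposited count of an entry was checked against the alignments: in all 10 libraries it equals the number of best-scoring alignments of reads on that entry, with 0 rows that differ. A read whose best score is tied between entries, or between repeats of 1 entry, therefore adds a count to each, so the counts sum to 1.36 to 1.75 per aligned read. Between 14.0% and 21.8% of reads in a library were tied. The line of totals equals the number of distinct aligned reads and was used as library size. A line that names no entry holds 0 reads and was left out. Between 1 and 9 entries per library occur in the alignments without a row in the count table; their reads (0.173% to 0.533% of a library) are not analysed here.

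Counts were turned into RPM (reads per 1000000 aligned reads). Because a species that matches the reference proteins less closely loses reads, levels were compared within a snake where the design allowed it. The non-pit libraries come from 2 species and were treated as 1 snake. The share of each species in a non-pit library was not established here. Reads of 3 libraries came from 2 sequencing lanes each; the mean chi-square between lanes, over entries with at least 50 counts and with an expectation of 1 for counting error alone, was 1.00 (rattlesnake large TG), 1.47 (python TG) and 1.07 (boa TG). The median identity of the alignments was 91.7% to 96.0% per library. The large and small trigeminal libraries of a snake were summed unless stated. For each pair, the log2 ratio was computed with 0.5 count added on each side, for entries with at least 20 counts. Its exact (Clopper-Pearson) 95% interval came from the binomial distribution of one library's count given both. An entry is called higher or lower by size when that whole interval lies beyond 2-fold (log2 of 1). A fold against a side with 0 counts is a lower bound against a floor of 3 counts over the libraries of that side, and the bound of the exact interval is given beside it. The labels name no molecular identifiers, so intervals and floors cover counting error only. With 1 library per group, no p-value between groups was computed from a pair.

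The 4 snakes served as replicates in 2 further tests, each on 8 values per entry (a trigeminal and a dorsal root value per snake). TG against DRG, with the snake as a block, used entries with at least 10 counts in at least 4 of the 8 values. The interaction of tissue with pit status used entries with at least 10 counts in at least 3 values. Both used edgeR (version 4.0.16) with TMM factors, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Snakes of different species stand for replicates here. With the snake as a block, p-values measure how the difference of TG and DRG varies between snakes. Variation between species and between single libraries cannot be told apart in them. DESeq2 (1.42.0), limma-voom (limma 3.58.1), other scaling, filters, uniquely assigned reads, fits that leave out each snake and, except in the interaction test, single trigeminal libraries were listed as alternatives before the data were examined. Counting each distinct alignment position once, using the sum of counts as library size, leaving out the rattlesnake small TG library, exchanging its label with that of the rattlesnake DRG library and, in the interaction test, single trigeminal libraries were added after seeing the data. R was version 4.3.3, and other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

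Entries were joined into a read-sharing family where at least 50% of the best-scoring reads of the smaller entry, with at least 10 reads, tied with the other. This gave 17877 families, of which 1024 held more than 1 entry (2621 entries, at most 27 in a family). Reads tied within a family cannot be assigned to a single member, but a member can also hold uniquely best reads. NP_989918, of a family of 20 entries, had 8310 counts and 6955 uniquely best reads in the boa DRG library.

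The methods were tested on simulated data. For the rattlesnake TG and DRG libraries, the 95% interval held the true ratio for 96.0% of 8777 entries, and 97.0% of 199 entries changed by a log2 of 3 were called, with 0 unchanged entries called. These counts were drawn as independent Poisson counts, the model behind the interval, without tied reads or extra spread between lanes. They check the computation and not the error of the real counts. In the across-snake test on 8613 entries edgeR recovered 83% of 100 entries changed by a log2 of 2 and 100% of 100 entries changed by a log2 of 5, with 16 unchanged entries called. In the interaction test on 9431 entries it recovered 6% and 68%, with 10 unchanged entries called. The counts for both tests were drawn from edgeR's own model, with means and dispersions fitted to these data. They too check the computation, and the shares recovered are not the power for real entries. In the real data XP_418294 had a log2 fold change of 5.88 across snakes and an adjusted p of 0.428 in edgeR.

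The rule for named genes, fixed beforehand, ranked entries by the interval bound nearest to 0, or by p in the across-snake test, and passed over entries without a gene name. The files pair no identifier with a name, so the ranking was kept. At most 2 identifiers per direction are given in each comparison, apart from XP_418294, which is also given where it is not among them. XP_418294 leads that ranking in rattlesnake, python and boa, and NP_990506 was picked after its values were seen. Gene lists of ion channels and cell types had been fixed for the same comparisons and could not be applied without names. The organism of the protein entries was not established here.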

Results

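The series holds 10 libraries of polyadenylated RNA from sensory ganglia of snakes, with 1 library per group. Trigeminal ganglia (TG) carry sensory fibres from the face, including those of the pit organs, facial pits with which some snakes sense infrared radiation. Dorsal root ganglia (DRG) carry sensory fibres from the trunk. The western diamondback rattlesnake (Crotalus atrox) and a pool labelled as non-pit snakes each gave a library of the large TG, the small TG and the DRG. The non-pit pool comes from 2 colubrid species, Pantherophis obsoletus lindheimeri and Masticophis flagellum testaceus. The ball python (Python regius) and the boa Corallus hortulana each gave a TG and a DRG library. The question set by the series is which transcripts mark the TG of snakes that detect infrared radiation, and its design text names the ion channel TRPA1. The deposited tables list protein entries by identifier and do not pair them with gene names, so no entry was matched to TRPA1 or to another gene here.

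Depth differed between libraries. Aligned reads numbered 784674 in the rattlesnake large TG library, 998174 in the small TG library and 1183208 in the DRG library. Libraries of the non-pit snakes held 765147 (large TG), 1323441 (small TG) and 524046 (DRG) aligned reads. The python libraries were the shallowest pair, with 691355 reads in the TG and 271230 in the DRG. The boa libraries held 6681710 and 2389400 reads. Between 9701 and 13027 of the 19474 protein entries had at least 1 count in a library. With 3 counts as the floor, an entry without a count allowed a level of up to 11.1 RPM (counts per 1000000 aligned reads) in the python DRG library and up to 0.449 in the boa TG library. No group had a replicate library, so every ratio between libraries lacks a replicate check, and the 95% exact (Clopper-Pearson) intervals given with levels and ratios cover counting error only.

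A single protein entry, XP_418294, had the ratio between TG and DRG with the counting interval farthest above 0 in each of the 3 pit-bearing snakes, with the labels as deposited. In the rattlesnake its level was 2388 RPM in the large TG (95% interval 2281 to 2499), 1092 in the small TG (1028 to 1159) and 6.76 in the DRG (2.92 to 13.3). In the python it was 9019 in the TG (8797 to 9244) and 140.1 in the DRG (99.1 to 192). In the boa it was 15405 in the TG (15312 to 15499), the 8th highest level of that library, and 89.1 in the DRG (77.6 to 102). The non-pit snakes gave 141 in the large TG (116 to 170), 294 in the small TG (265 to 325) and 143 in the DRG (113 to 179). With the large and small TG libraries summed, XP_418294 was 231-fold higher in TG than in DRG in the rattlesnake (95% interval 125 to 570; log2 ratio 7.85, and -0.19 with the labels of the rattlesnake small TG and DRG libraries exchanged), 63.5-fold in the python (46.8 to 91.1) and 172-fold in the boa (151 to 199). For the non-pit snakes the ratio was 1.65-fold (1.30 to 2.15), and its interval did not lie wholly beyond 2-fold.

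**Figure D1:**
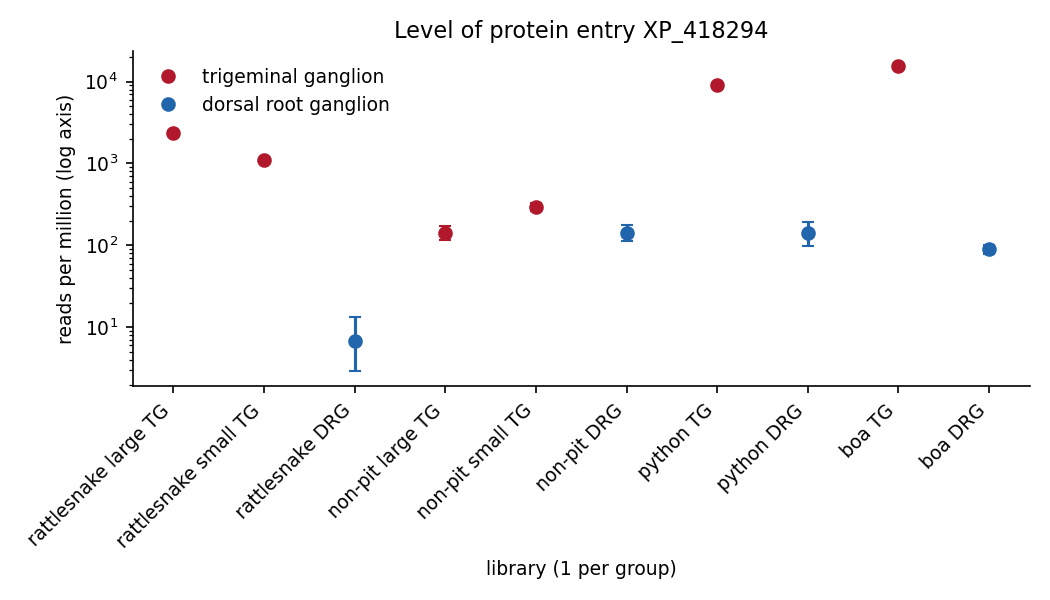
Level of protein entry XP_418294 in each of the 10 libraries, in RPM (reads per 1000000 aligned reads) on a log axis, with trigeminal libraries in red and dorsal root libraries in blue. Points are single libraries and bars are exact 95% counting intervals; the TG libraries of rattlesnake, python and boa lie between 1092 and 15405, and those of the non-pit snakes at 141 and 294. Libraries are shown under their deposited labels; with those of the rattlesnake small TG and DRG exchanged, the rattlesnake log2 ratio of TG to DRG is -0.19.

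The reads behind these levels of XP_418294 were each assigned to that entry alone. In the boa TG library they started from 4835 distinct alignment positions and covered 920 residues of the entry, whose aligned part reached residue 1010. In the rattlesnake DRG library the entry had 8 counts, so the rattlesnake ratio rests on a small number of reads. With each alignment position counted once, the log2 ratio of TG to DRG was 6.99 in the rattlesnake, 4.50 in the python, 3.43 in the boa and 0.69 in the non-pit snakes. The boa TG library held 102933 reads on its 4835 positions. Positions on an entry are limited, so this count can lower the ratio of an abundant entry without repeated fragments.

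The next comparison asked which entries exceeded the non-pit ratio of TG to DRG in all pit-bearing snakes. For each entry the smallest log2 ratio of TG to DRG among rattlesnake, python and boa was set against that of the non-pit snakes. The difference exceeded 1 for 451 of 11568 entries, and 68 of these had a log2 ratio above 1 in each pit-bearing snake. By read-sharing families the 451 entries made 403 and the 68 made 59. The minimum count applied to all libraries together, so some of these ratios rest on few or no counts. XP_001233293, XP_001231380, XP_430457 and XP_425562 passed with 0 counts in every non-pit library. Their non-pit log2 ratio of -1.99 reflects depth alone, so an excess over it is not shown. XP_001233293 also had only 4 counts in the python TG against 0 in the DRG. XP_418294 ranked first among the 68, with a difference of 5.26 (2.75 with each alignment position counted once), and 10th among all 11568 entries. This rests on the rattlesnake labels: with those of the small TG and DRG libraries exchanged, a setting chosen after seeing the data, its difference was -0.92 and it was not among the 230 entries that passed both limits. Entries above it in the full ranking had a smallest pit-snake log2 ratio of 0.34 or less, and were placed there by low ratios in the non-pit snakes. Among the 8854 entries with 100 or more counts, the highest smallest ratio after that of XP_418294 (5.99) was 3.15, in entry XP_421809. Its ratio in the non-pit snakes was not measurable at this depth, with 9 counts in TG and 0 in DRG. Without the rattlesnake small TG library, a setting chosen after seeing the data, 117 entries in place of 68 passed both limits.

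**Figure D2:**
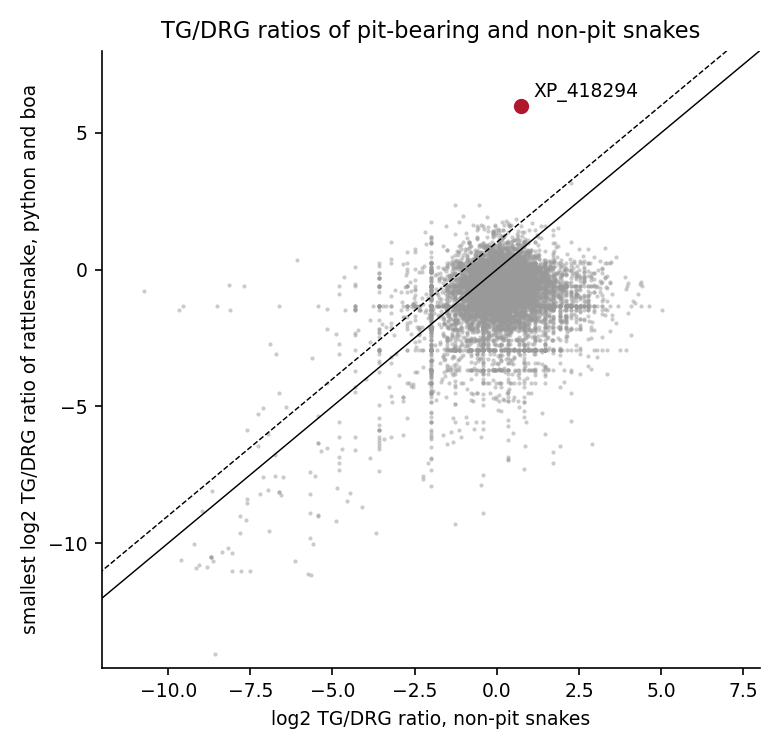
Each point is 1 of 11568 protein entries, with the log2 ratio of TG to DRG in the non-pit snakes on the horizontal axis and the smallest such ratio among rattlesnake, python and boa on the vertical axis. The solid line marks equal ratios and the dashed line a difference of 1; XP_418294 lies at 0.73 and 5.99 with the labels as deposited, apart from the other entries, and at 0.73 and -0.19 with the rattlesnake small TG and DRG labels exchanged.

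The test of whether the ratio of TG to DRG differed between the 3 pit-bearing snakes and the non-pit snakes, fitted with edgeR's quasi-likelihood method on 8 values per entry, gave no entry past an adjusted p of 0.05 among 9431 entries. At an unadjusted p under 0.05, 69 entries were higher and 95 lower in the pit-bearing snakes. limma-voom also gave 0 entries, and DESeq2 gave 2, both higher. XP_418294 had a fitted log2 difference of 6.37, with an adjusted p of 1 in edgeR and 4.68e-06 in DESeq2. The other entry was NP_990506, with 405 counts in the non-pit DRG library and at most 31 in any other library (adjusted p of 0.0016 in DESeq2 and 0.834 in edgeR; in edgeR 0.00734 without the boa and 0.0351 without the rattlesnake small TG library). The lone non-pit pair was assumed to vary like the other snakes. Without the rattlesnake, edgeR gave 12 higher and 12 lower entries, with an adjusted p of 0.00355 for XP_418294.

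In the rattlesnake, 247 of 8755 entries were higher in TG than in DRG with the whole interval beyond 2-fold, and 130 were lower. Members of a read-sharing family are counted singly in such numbers, and here the entries fell in 209 and 112 families. Beside XP_418294, entry XP_426430 was 32.4-fold higher in TG (15.1 to 110.4), with 268 against 5 counts; its log2 ratio of 5.02 was 6.01 without the small TG library and 2.89 with that library alone. Lower entries included NP_989879, with 36 counts in the DRG library and 0 in both TG libraries, at least 18.1-fold lower in TG (interval bound 14.0), and XP_001234944, with 33 and 0 counts, at least 16.6-fold lower (interval bound 12.7); the folds written as at least are against a floor of 3 counts over the libraries of the empty side, and the exact interval reaches to the bound given. The small TG library differed from the large one, as given below, and 53 of the 247 higher entries belonged to the group of 62 entries described there. Without the small TG library the counts were 197 higher and 209 lower, of which 82 and 64 were among the entries called with both libraries. With the labels of the small TG and DRG libraries exchanged, a setting chosen after seeing the data, 563 entries were higher and 293 lower, and the log2 ratios became 1.82 for XP_426430, 5.21 for NP_989879 and 5.09 for XP_001234944, turning the direction of the last 2. With TMM factors 309 entries were higher and 86 lower, and with DESeq2 size factors 331 and 78. The ratios of all entries had a median log2 of -0.15 with total reads, 0.01 with TMM factors and 0.06 with DESeq2 size factors.

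In the non-pit snakes, 36 of 8367 entries were higher in TG than in DRG and 116 were lower, in 35 and 84 read-sharing families. Entry NP_989549 was 32.4-fold higher in TG (12.8 to 184), with 451 counts against 3, and XP_414734 was 15.6-fold higher (6.13 to 88.7), with 217 against 3. Entry NP_989559, of a read-sharing family of 20 entries, was 532-fold lower in TG (249.6 to 1807). NP_989510 had 215 counts in the DRG library and 0 in both TG libraries, at least 286-fold lower in TG (interval bound 230.3). The read names of both non-pit TG libraries carry another instrument prefix than those of the DRG library, so tissue and sequencing batch cannot be told apart in this comparison. Both libraries carry the same prefix in each of the python and boa pairs, as do the 3 rattlesnake libraries. With the large TG library alone 18 entries were higher, and with the small TG library alone 62.

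In the python, 607 of 5385 entries were higher in TG and 196 were lower, in 522 and 147 read-sharing families. After XP_418294, the entry whose interval lay farthest above 0 was XP_422478, with 226 counts in TG and 0 in DRG, at least 29.6-fold higher (interval bound 23.8). NP_990748 had 3349 counts in the DRG library and 0 in TG, at least 2845-fold lower in TG (interval bound 2313). The same entry had 4498 counts in the rattlesnake small TG library and 5 in the large TG library. NP_001013415, from the read-sharing family of 20 entries named above for NP_989559, was 2082-fold lower in TG (981 to 7056). The median log2 ratio of all entries was 0.54 with total reads, 0.28 with TMM factors and 0.15 with DESeq2 size factors. The counts moved to 406 higher and 246 lower with TMM factors, and to 338 and 277 with DESeq2 size factors.

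In the boa, 668 of 10412 entries were higher in TG and 670 were lower, in 590 and 594 read-sharing families. XP_001233105 followed XP_418294 with 460 counts in TG against 1 in DRG, a ratio of 109.8-fold (29.4 to 6511). XP_425360 was 2292-fold lower in TG, with 1 count against 1229 (616 to 135854), and NP_989918 was 762-fold lower (542 to 1149); both belong to the same read-sharing family of 20 entries. With each alignment position counted once, 323 entries were higher and 385 lower.

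Between the summed TG libraries of the rattlesnake and of the non-pit snakes, 436 of 9388 entries were higher in the rattlesnake and 565 were lower. This comparison between species also moves with how closely each species matches the reference proteins. XP_418294 was higher in the rattlesnake, at 1663 RPM against 238 in the summed non-pit TG libraries (log2 ratio 2.80, 2.67 to 2.94). The intervals farthest above 0 were those of NP_989559, 3277-fold higher in the rattlesnake (1544 to 11103), and XP_415578, 2147-fold higher (1325 to 4067), both of the family of 20 entries. Nearly all of these counts came from the rattlesnake small TG library, which held 15370 of those of NP_989559 against 14 in the large TG, and 26547 of those of XP_415578 against 22. Without that library the log2 ratio of XP_415578 was 2.05 in place of 11.07. NP_989549 had 0 counts in the rattlesnake and 451 in the non-pit snakes, at least 128-fold lower (interval bound 104). XP_418980 was 77.4-fold lower (36.2 to 263), and all of its reads tied with another entry. Without the rattlesnake small TG library 273 entries were higher and 324 lower. With TMM factors 568 entries were higher and 378 lower, and with DESeq2 size factors 618 and 309.

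The large and small TG libraries were close in the non-pit snakes and far apart in the rattlesnake. Over the 8854 entries with 100 or more counts, which are not independent replicates, Spearman's rho between large and small TG was 0.963 in the non-pit snakes and 0.794 in the rattlesnake. The rattlesnake small TG library correlated more closely with the rattlesnake DRG library (0.863), and so did the large TG library (0.877). In the rattlesnake 674 of 7549 entries were higher in the large TG and 379 were lower, against 3 and 28 of 7844 in the non-pit snakes. XP_425187 was 33.7-fold higher in the rattlesnake large TG (17.1 to 90.7), and XP_001236722 was 24.2-fold higher (10.2 to 101). Entries XP_415578 and XP_001231409, of the family of 20, were 928-fold (626 to 1514) and 932-fold (612 to 1588) lower there than in the small TG. In the non-pit snakes NP_990476 was 6.10-fold higher in the large TG (2.97 to 15.1) and XP_001231536 was 5.77-fold lower (5.48 to 6.09). With each alignment position counted once the log2 ratio of XP_001231536 changed from -2.53 to -0.41. Its aligned part reached residue 148, and 15396 reads lay at 1367 positions in the small TG and 1541 at 691 in the large TG. Positions on a short entry are limited, so this count can shrink a ratio without repeated fragments.

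A group of 62 entries, in 39 read-sharing families, was chosen after seeing the data by its levels in python and boa alone: each was over 8-fold higher in DRG than in TG in both snakes and had at least 20 counts in both DRG libraries. These entries took 17.5% of the counts in the python DRG library and 4.14% in the boa DRG library, against 0.0707% and 0.0254% in the TG libraries. A tied read counts for each entry of a family, and among uniquely best reads the shares were 8.66% in the python DRG library, 2.41% in the boa DRG library and 6.95% in the rattlesnake small TG library. In the rattlesnake they took 15.5% of the counts in the small TG library, 1.70% in the DRG library and 0.103% in the large TG library. Their share in the non-pit snakes was 1.93% in the DRG, 0.152% in the small TG and 0.0378% in the large TG. All 62 entries were higher in the small than in the large TG of the rattlesnake, by a median log2 of 7.98 (quartiles 6.37 and 9.45). Of the 62, 37 were higher in the small TG of the non-pit snakes, and the median log2 over all 62 was 0.37 (quartiles -0.79 and 1.53). All 62 were among the 196 entries lower in TG in the python and the 670 in the boa, where the group was chosen. The group also held 48 of the 116 lower entries of the non-pit snakes and 6 of the 130 of the rattlesnake. Whether RNA of another tissue raised these entries in the DRG libraries was not tested.

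**Figure D3:**
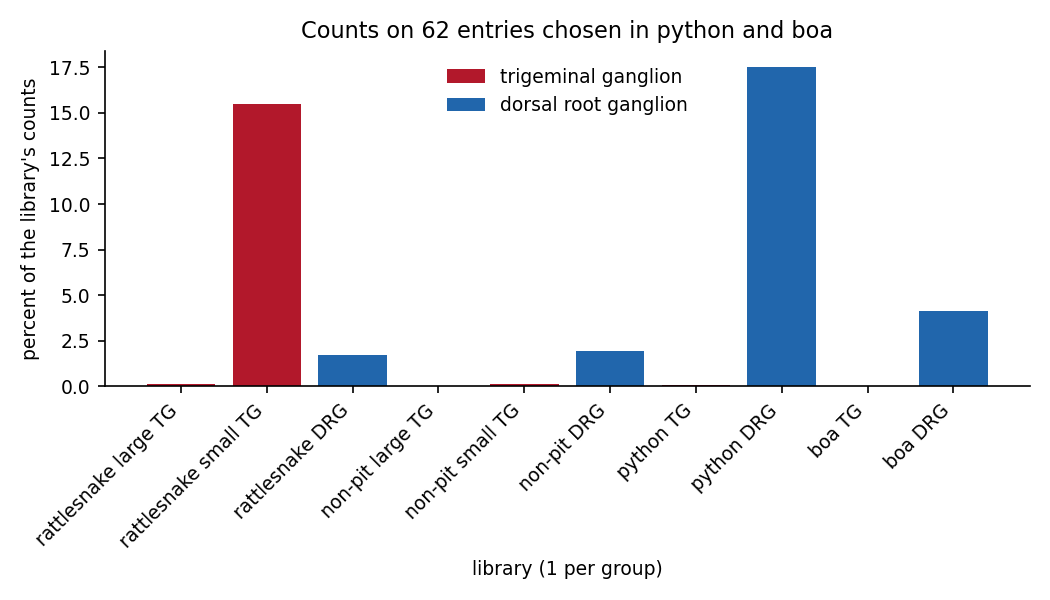
Percent of each library's counts that fell on the 62 entries chosen for high levels in the DRG libraries of python and boa, with trigeminal libraries in red and dorsal root libraries in blue. Bars are single libraries without error bars; the rattlesnake small TG library (15.5%) is the one trigeminal library above 1%.

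Across the 4 snakes, TG was tested against DRG with the snake as a block. By edgeR's quasi-likelihood test 0 of 8613 entries rose and 1 fell at an adjusted p of 0.05, with 379 higher and 329 lower entries at an unadjusted p under 0.05. The entry that fell in TG, NP_989926, had an adjusted p of 0.00495 and was lower in 4 of 4 snakes. It had 60, 62, 10 and 80 counts in the DRG libraries of rattlesnake, non-pit snakes, python and boa. In the TG libraries it had 2 counts in the rattlesnake small TG and 0 in each of the others. The smallest p values among higher entries were those of XP_421809 (log2 fold change 3.66, SE 0.52, adjusted p of 0.112 in edgeR) and NP_001038116 (2.87, SE 0.48, adjusted p of 0.303 in edgeR). XP_421809 was higher in rattlesnake, python and boa, its direction in the non-pit snakes being below what the depth could show. NP_001038116 was higher in 4 of 4 snakes by its point ratios. In the non-pit snakes it had 7 and 14 counts in the large and small TG against 1 in the DRG. The counting intervals of these levels overlap, so its direction there is uncertain too. XP_418294 had a log2 fold change of 5.88 and an adjusted p of 0.428 in edgeR, also higher in 4 of 4 snakes. DESeq2 gave 21 higher and 65 lower entries, in 21 and 43 read-sharing families, and limma-voom gave 0 and 1 entries. The named higher entries passed in DESeq2, with an adjusted p of 8.29e-05 for XP_421809 and 0.000463 for both NP_001038116 and XP_418294. Over all alternatives the adjusted p ranged from 4.26e-07 to 1 for XP_421809, 5.65e-06 to 1 for NP_001038116 and 7.19e-06 to 1 for XP_418294. XP_421809 passed in 6 of its 18 alternatives, NP_001038116 in 6 of 19 and XP_418294 in 5 of 20. Among those of XP_421809 were edgeR with all 10 libraries entered separately (0.039) and with the large TG libraries alone (0.000333).

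The number of entries past the threshold across snakes changed with the filter, the tool and the rattlesnake small TG library. With that library kept, edgeR gave 107 higher and 132 lower entries without the filter, and DESeq2 21 and 65 with it. With the large TG libraries alone, edgeR gave 90 higher and 168 lower entries, and 54 of the 168 belonged to the group of 62 entries. NP_989926 was among them, and XP_418294 had an adjusted p of 0.00926. Without the rattlesnake small TG library alone the counts were 58 and 120, and without the rattlesnake 60 and 145. Of the 258 entries called with the large TG libraries, 155 were also called without the rattlesnake. Leaving out the non-pit snakes or the boa ended the call of NP_989926 (adjusted p of 0.136 and 0.114 in edgeR), with a fitted log2 fold change of -6.97 and -7.10 in place of -7.74. With the labels of the rattlesnake small TG and DRG libraries exchanged, edgeR gave 32 higher and 132 lower entries, and NP_989926 was not called (log2 fold change -4.53, adjusted p of 0.175).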

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

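The tests of explanations in this part were chosen after the results were seen.

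XP_418294 was singled out because DESeq2's test of the difference between pit-bearing and non-pit snakes gave an adjusted p of 4.68e-06, with a ratio of TG to DRG higher in each of 3 pit-bearing snakes than in the non-pit pair; edgeR's adjusted p was 1. Tied reads as the source are argued against, since with uniquely best reads alone the smallest log2 ratio of the pit-bearing snakes was 5.89. Repeated reads of a few fragments are argued against as the whole source, since the smallest ratio was 3.43 when each alignment position counted once. A lower share of the main cell type in the DRG libraries is argued against, since it would carry many transcripts of that type along: of 2888 other entries with counts enough to show it, 1 came within a log2 of 1 of XP_418294 in both python and boa (5.37 against 5.99), where 10 were taken as the least, and the 99th percentile was 2.38. With the rattlesnake as labelled, the next entry stood at 3.15. XP_418294 was picked for its high ratios in these same libraries, which can by itself make near neighbours fewer. The limit of 10 was also set after the results were seen, so this argument is a weak one. A cell type marked by few transcripts stays open, since no markers were examined. An exchange of the rattlesnake small TG and DRG labels bears on the rattlesnake part alone, and would bring its log2 ratio to -0.19. Values of 9 other entries, given under Other observations, argue against an exchange without ruling it out. The ratios of python and boa do not rest on those labels. A difference between the TG and DRG of pit-bearing snakes in this transcript is likewise open, found and examined on the same libraries and with a lone non-pit pair whose TG and DRG were sequenced under different read-name prefixes.

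NP_990506 was singled out by the same DESeq2 test, with an adjusted p of 0.0016. edgeR gave 0.834, and passed the entry without the filter (8.93e-05), without the boa (0.00734) and without the rattlesnake small TG library (0.0351); over all alternatives the adjusted p ranged from 8.93e-05 to 1. It belongs to 8 entries with at least 20 counts in the non-pit DRG library, outside the group of 62. By point ratios they were there over 32-fold above the non-pit small TG. They were likewise over 16-fold above the non-pit large TG and the rattlesnake and python DRG. Against the floor of 3 counts these limits are not shown for every entry. NP_990369, NP_989739, XP_426690 and NP_989776 had 0 counts in the python DRG, which allows 11.1 RPM. Their non-pit DRG levels of 64.9, 85.9, 143 and 147 RPM are too low to show 16-fold over that. NP_990369 also falls short of 32-fold over the non-pit small TG floor of 2.27 RPM. The non-pit DRG library held 1251 counts on the 8 entries, 0.164% of its total, against 19 in both non-pit TG libraries. The boa was not part of the rule. NP_989776 had 85 counts in the boa TG and 43 in the boa DRG, against 77 in the non-pit DRG. Reads of the organism of the reference proteins, as a candidate source, would match with an identity near 100%; the median identity of the 8 entries was 86.5%, and the mean over the library was 89.8%. Repeated reads of a few fragments are argued against by 1.20 uniquely best reads per alignment position, against 1.21 over the library. Another tissue in the pool, the sequencing batch of that library and a difference between the snakes remain open and were not tested. The shares of the 2 pooled species in that library were not established either.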

How the results depend on the processing

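Counting each alignment position once (distinct positions), library size as the sum of counts, leaving out the rattlesnake small TG library, exchanging its label with that of the rattlesnake DRG (exchanged labels) and, for the interaction, single TG libraries were chosen after seeing the data; the other settings were listed before. Of 198 alternative values of the counts, 128 lay within 1.5 times the reported count and 70 did not. Of 321 alternative values for named entries, 4 turned the direction of a called ratio or of the pit excess, all with exchanged labels. The ratio of XP_418294 in the non-pit snakes, which was not called, also turned, from a log2 of 0.73 to -0.02 with the large TG library alone. Tests of gene lists were not run, since no entry has a name. No paired analysis by replicate number was possible because the labels give none; the snake was the block. The causes of the shifts below were not tested unless stated.

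For TG over DRG in the rattlesnake, the lower entries numbered 86 with TMM factors, 78 with DESeq2 size factors, 209 with the large TG library alone (the same as without the small one), 485 with the small one alone and 58 with distinct positions. A minimum of 100 reads, under which fewer entries are compared, left 154 higher entries. In the non-pit snakes that minimum left 13 higher and 70 lower entries, and the large or small TG library alone gave 18 or 62 higher. In the python the higher entries numbered 338 with DESeq2 size factors, 404 with the minimum of 100 reads and 344 with distinct positions. In the boa distinct positions gave 323 higher and 385 lower, and the minimum of 100 reads 398 lower. For rattlesnake TG over non-pit TG the higher entries numbered 240 with the minimum of 100 reads, 235 with the large TG libraries and 273 without the rattlesnake small TG. The lower ones numbered 309 with DESeq2 size factors, 221 with the large TG libraries, 988 with the small ones, 272 with distinct positions and 324 without the rattlesnake small TG. For large over small TG, distinct positions left 347 higher and the minimum of 100 reads 221 lower in the rattlesnake. In the non-pit snakes the 3 higher entries became 1 with the minimum of 100 reads or distinct positions and 5 with a minimum of 1 read or uniquely best reads; the minimum of 100 reads left 12 lower. For the pit excess, the minimum of 100 reads left 225 entries, and those with every pit-snake ratio above 1 numbered 120 with the large TG libraries, 39 with the small ones and 117 without the rattlesnake small TG.

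With exchanged labels, TG over DRG in the rattlesnake gave 563 higher and 293 lower, rattlesnake TG over non-pit TG 300 lower, large over small TG in the rattlesnake 197 higher and 209 lower, and the pit excess 230 entries with every pit-snake ratio above 1. The rattlesnake log2 ratio became -0.19 for XP_418294, 5.21 for NP_989879 and 5.09 for XP_001234944, and the pit excess of XP_418294 -0.92.

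Across snakes, the higher and lower entries numbered 21 and 65 with DESeq2, 107 and 132 without a filter, 90 and 168 with the large TG libraries, 58 and 120 without the rattlesnake small TG, and 32 and 132 with exchanged labels. With all 10 libraries entered separately 1 rose. The lower count was 0 with at least 50 reads, uniquely best reads, distinct positions, the small TG libraries or the 3 pit-bearing snakes. Leaving out a snake in turn gave 0 to 60 higher and 0 to 145 lower. For the interaction the higher and lower entries numbered 9 and 2 without a filter; DESeq2 gave 2 higher (XP_418294 and NP_990506), the fit without the rattlesnake small TG gave 2 (NP_989510 and NP_990506, with XP_418294 at an adjusted p of 0.162), and leaving out a snake in turn gave 0 to 12 higher and 0 to 12 lower. XP_418294 kept its direction in the 3 pit-bearing snakes under every alternative run except exchanged labels; otherwise its log2 ratio ranged from 6.99 to 8.38 in the rattlesnake, 4.50 to 5.99 in the python and 3.43 to 7.44 in the boa, and from -0.02 to 1.03 in the non-pit snakes. NP_989926 lost its call across snakes without the non-pit snakes (the same fit as the 3 pit-bearing snakes), without the boa, with the small TG libraries and with exchanged labels (adjusted p of up to 0.175); with at least 50 reads, uniquely best reads or distinct positions it fell under the filter and was not tested. The adjusted p of XP_418294 in the interaction ranged from 4.68e-06 to 1. Depth limits the python DRG library most, where an entry without a count may lie at up to 11.1 RPM.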

Other observations

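The tests in this part were chosen after the results were seen; for that of the 108 entries, the outcome expected under each view was written before its value was computed. A second group of 9 entries was found by its counts in the other snakes: at least 8 counts in the DRG libraries of non-pit snakes and boa, at least 2 in that of the python, at most 4 in their TG libraries together, and none of the 62 entries described above, of which 5 more met these limits. In the rattlesnake these entries had 297 counts in the DRG library, 2 in the large TG and 11 in the small TG. NP_989926, the entry that fell in TG across snakes, was among them, with 60 counts in the rattlesnake DRG library and 2 in the small TG.

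The rattlesnake small TG library stood apart from the large one. RNA of another tissue in the small TG library is a candidate explanation: the 62 entries chosen in python and boa had a median log2 ratio of small to large TG of 7.98 in the rattlesnake. Without names the tissue was not identified. A difference between large and small ganglia of the rattlesnake itself stays open and was not tested.

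An exchange of the rattlesnake small TG and DRG libraries is a further candidate explanation, and the values go both ways. The 9 entries had a median log2 ratio of small TG to DRG of -4.35, against an exchange, and XP_418294 had 1092 RPM in the small TG and 6.76 in the DRG. The 5 entries set aside from that group were all higher in the small TG, the median over all 14 was -3.28, and the 62 entries had a median of 3.65, with 56 higher in the small TG. In addition, 108 entries had a log2 ratio of TG to DRG above 1 in non-pit snakes, python and boa. In the rattlesnake their median log2 ratio was -0.82 for small TG to DRG, against 0.59 for large TG to DRG. An exchange would lower the first of these ratios. RNA of another tissue that takes up counts of the small TG library would lower it too, so this value favours neither. The 108 entries therefore cannot tell RNA of another tissue from an exchange. The 9 entries argue against an exchange alone: 0 were higher in the small TG than in the DRG (quartiles -5.04 and -3.53). They held 297 counts in the rattlesnake DRG, 11 in the small TG and 2 in the large TG. The 5 and the 62 entries go the other way, but RNA of another tissue could raise them too. An exchange is not ruled out, since the 9 were picked without those entries. Were the labels exchanged, XP_418294 would stand at 2388 RPM in the large TG and 6.76 in the small TG, or 956 in both summed, against 1092 in the DRG, a log2 ratio of -0.19 (-0.30 to -0.08), so its higher level in the rattlesnake TG holds with the labels as deposited.

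Splits of the 8 tissue values bear on the across-snake counts. With the snake as a block, the 8 splits that part TG from DRG in all 4 snakes compare with the real one, too few for a share under 0.05. With both TG libraries the real split gave 1 entry and 2 of the 8 splits gave as many; the highest other gave 78 and sets the rattlesnake TG with the DRG of the other snakes. With the large TG libraries alone the real split gave 258 entries and the highest other 0, so 1 of the 8 gave as many. Among all 32 splits that could be fitted with both TG libraries, the highest gave 525 entries. That split parts TG from DRG in python and boa and leaves the other snakes unparted. With the snake as a block, it compares TG with DRG in python and boa alone. Its count therefore reflects the tissue labels of those snakes and gives no measure of what random labels would yield. With the large TG libraries alone that split gave 76 entries, fewer than the 258 of the real one.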
